A study of Arabidopsis thaliana with 30 samples.

How the data were processed

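The analysis used 30 Affymetrix ATH1 arrays of Arabidopsis rosette leaves, from 2 genotypes (Col-0 and the catalase mutant cat2-1) in 5 conditions with 3 arrays each. Per the labels, plants grew for 5 weeks at 3000 ppm CO2 in short days (8 h light, 16 h dark) and were sampled there (hCO2) or after 2 or 4 days in air (400 ppm) in short days (SD2, SD4) or in long days of 16 h light (LD2, LD4), always 7 h into the light. No group had long days at 3000 ppm, so comparisons of LD2 and LD4 with hCO2, called air here for short, change air and day length together. Each array was a pool of leaves from different plants, so the arrays of a group were separate biological samples. The treatment label of the Col-0 hCO2 arrays gave 300 ppm where the protocol gave 3000 ppm, and the protocol value was used.

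The deposited values were log2 signals of 22810 probe sets, made with RMA in the affy package per the submitters' processing notes, with versions not given in the sources used here. They were used as deposited. The 64 control probe sets were set aside and 22746 were tested. In the probe set annotation used here 13513 of these had exactly 1 gene, 503 had several and 8730 were not listed. Only probe sets with exactly 1 gene were named, 13356 distinct genes in all, and others were reported by identifier. CAT1, CAT2 and CAT3 had 0 probe sets of their own in it. Probe sets were the unit of every count.

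A linear model with a mean for each of the 10 groups was fitted in limma 3.58.1 (R 4.3.3) to all 30 arrays, with moderated t tests for 23 comparisons: air against CO2 in Col-0, cat2 against Col-0 in each condition, long against short days, day 4 against day 2, and the interactions of genotype with air and with day length. P values were adjusted by Benjamini-Hochberg within a comparison over 22746 probe sets, and an adjusted p below 0.05 was a call. The genes named for each comparison were the called single-gene probe sets with the largest log2 difference in each direction, 4 for air and day length, 5 for genotype and 2 for time. In comparisons of a pair of groups these genes also had no overlap between the arrays of the groups, which happens by chance for 10% of unchanged genes with 3 arrays against 3. Members of gene lists were named beside them.

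Gene lists were tested with limma camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, both adjusted by Benjamini-Hochberg within a comparison. Of 23 lists fixed before the data were examined, holding 400 genes, 61 genes had a probe set of their own and 12 lists had at least 3 measured genes and were tested. A further 18 lists were written from gene symbols after the annotation had been opened, and were adjusted apart. For the fixed lists, members were also counted after adjusting over the list alone. Of 276 tests of fixed lists 66 were called and 33 with an estimated correlation, and of 414 tests of added lists 80 and 12.

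The comparisons, the test, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were a replicate block, a fit of only the arrays compared, a filter of dim probe sets (mean log2 below 5), a further quantile normalization, centring of each array on its median, eBayes with trend and robust options, array weights, single arrays left out, and only 1 probe set per single gene. Covariates from the BioB spike-in, the actin 3' minus 5' difference and the 25S ribosomal RNA control, array weights estimated gene by gene, the replicate block in a fit of only the arrays compared, list tests after another scaling, and shuffles of the arrays for interactions were added after the data had been seen.

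The replicate numbers were checked for pairing by correlating the residuals of arrays with the same number. Every such correlation was above 0.1 only for cat2 against Col-0 at SD4 (0.62, 0.31 and 0.63) and at LD4 (0.44, 0.45 and 0.22). For Col-0 at LD4 against SD4 they were negative (−0.51, −0.46 and −0.5), so values of this size need not mark paired arrays. The labels do not say what arrays of the same number share. No array columns were identical. Correlations between arrays of a group lay between 0.9845 and 0.9965, and the first 4 principal components held 26.6%, 20.3%, 12.5% and 11% of the variance.

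The fit was tried on simulated data with 200 of 22746 probe sets changed. For cat2 against Col-0 at SD2 it found 35 of 50 changes of 1.5-fold, 48 of 50 of 2-fold and all 50 of 4-fold and of 8-fold, with 16 false calls. For the interaction of genotype and air at SD2 it found 23, 42, 50 and 50, with 7 false calls. The simulated noise was independent between probe sets, while the real arrays of a group differed along shared components (31.1% of that variance on the first). The false calls are thus no measure of those in the real comparisons. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.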

Results

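After 2 days of air in short days the leaves of cat2-1 had higher transcripts than Col-0 for 9 of 21 small heat shock proteins and co-chaperones and 4 of 5 oxidative stress markers. Of 47 UDP-glycosyltransferases 11 were higher and 2 lower (list adjusted p = 0.0349, and adjusted p = 0.443 with an estimated correlation). In 3000 ppm CO2 only 3 of 22746 probe sets were called between the genotypes, a count that rose when arrays were weighted. In long days many of the short-day gains were smaller in cat2, and COR15A, which codes for a cold-regulated chloroplast protein, fell below its Col-0 level by day 4. In Col-0, air raised all 3 dehydration genes in short days (adjusted p = 0.15 with an estimated correlation at day 2, 0.0327 at day 4). After 4 days of air and long days all 9 ATG8 autophagy genes were higher than at CO2 (adjusted p = 0.339 with an estimated correlation), as were 2 of 4 sugar starvation genes. In short days 3 ATG8 genes rose at day 2 and none at day 4. Their list still shifted up at day 4 (median 0.32, list adjusted p = 0.00215, 0.527 with an estimated correlation). Between long and short days at day 4, 4 of the 9 were called. The CO2 plants had short days, so long-day groups differ from them in both air and day length, and these were not separated. A gene is said to rise or fall where limma with Benjamini-Hochberg gave an adjusted p below 0.05. Values are log2 differences, those after ± are their standard errors, and every group had n = 3 arrays.

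**Figure D1:**
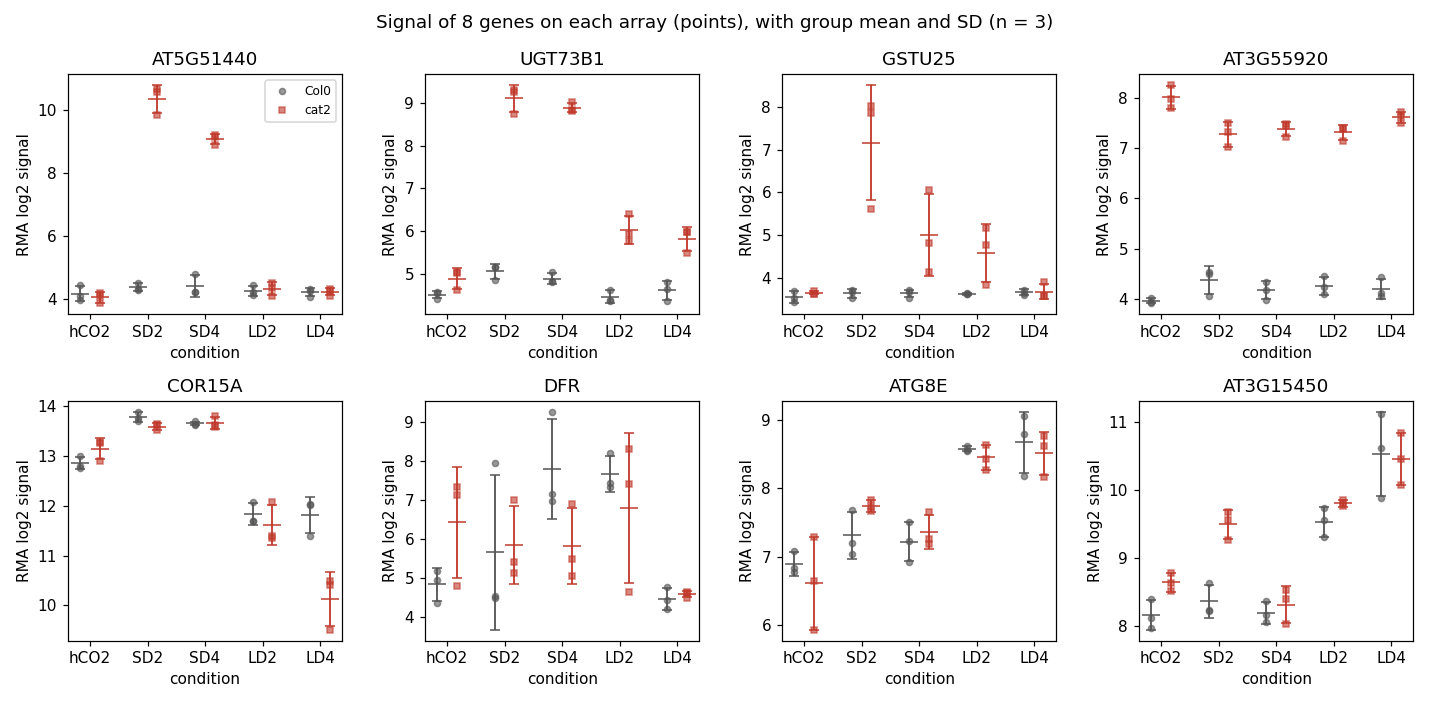
RMA log2 signal of 8 genes on each of the 30 arrays, with group means and standard deviations (n = 3 per group). AT5G51440 averaged 10.36 in cat2 and 4.37 in Col-0 after 2 days of air in short days, and 4.17 in Col-0 at 3000 ppm CO2.

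**Figure D2:**
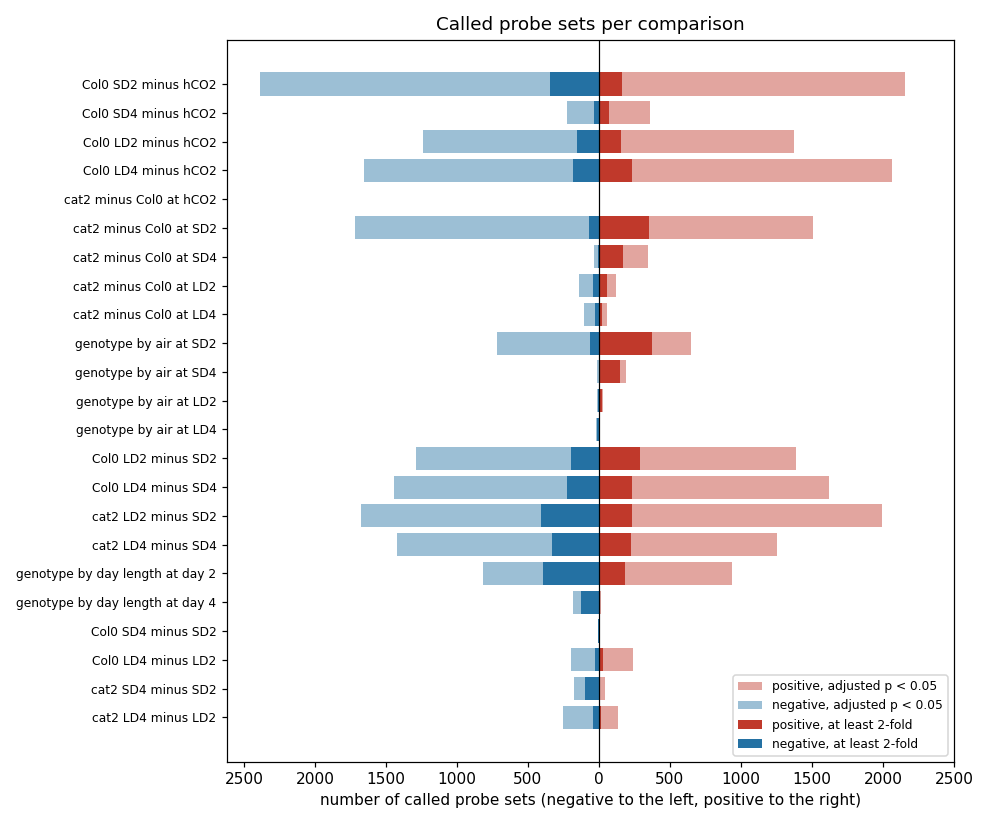
Number of probe sets that rose or fell in each of the 23 comparisons, from 4546 in Col-0 after 2 days of air in short days to 3 between the genotypes at 3000 ppm CO2, with those of at least 2-fold in darker colour.

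At 3000 ppm CO2 few probe sets were called between the genotypes, and 1 gene had a large gain. AT3G55920, which codes for a cyclophilin-type peptidyl-prolyl isomerase, rose by 4.04 ± 0.15 in cat2 (adjusted p = 3.55e-15, limma with Benjamini-Hochberg), and AT1G77960 rose by 0.94 ± 0.15. The only probe set that fell, 253174_at, had no gene in the annotation used here, and it was lower in cat2 at CO2 (−3.94 ± 0.15). It was also lower after air in short days (−3.39 at day 2, −3.36 at day 4) and in long days (−4.01, −4.29). These were the only 3 calls at CO2, while 1531 probe sets had an unadjusted p under 0.05, and 70 were called when cat2 replicate 3 was left out. With array weights 7694 were called, 1847 with weights estimated gene by gene, and another split of these 6 arrays gave 3134, so a low count here is no measure of likeness. No probe set was named for CAT2 in that annotation, so the transcript of the mutated gene could not be picked out here. An unlisted probe set, 253174_at or another, may measure it.

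No member of any gene list was called at CO2, although 7 lists passed the list test of small shifts. The 21 genes of immune receptors and defence signalling had a median of −0.50 in cat2 (adjusted p = 1.44e-07, and adjusted p = 0.282 with an estimated correlation). Of these genes 17 followed the largest component of the differences within groups, as did all 18 of endoplasmic reticulum folding, and on it cat2 replicate 3 (0.42) and Col-0 replicate 2 (−0.35) stood furthest apart among the CO2 arrays. Without replicates 1, 2 and 3 in turn the immune median was −0.32, −0.57 and −0.54, each time with a call. Medians were −0.30 for glucosinolate synthesis (adjusted p = 0.00407, 0.149 with an estimated correlation) and −0.33 for oxidative stress markers (0.0131, 0.149). Endoplasmic reticulum protein folding had a median of −0.16 (0.00393, 0.699). Small positive medians were seen for antioxidant enzymes (0.15; 0.0177, 0.149), anthocyanin and flavonoid genes (0.71; 0.0483, 0.357) and abscisic acid and dehydration genes (0.52; 0.0371, 0.233). Adjusted over the list alone, 3 glucosinolate genes and 2 oxidative stress markers fell and 1 antioxidant gene rose.

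After 2 days of air in short days the mutant leaf switched on a heat shock and oxidative stress program. AT5G51440, which codes for a small heat shock protein, rose by 5.99 ± 0.18 (adjusted p = 4.7e-17, limma with Benjamini-Hochberg). AT1G10585, a bHLH transcription factor gene, rose by 4.91 ± 0.40, AT2G29500, another small heat shock protein gene, by 4.38 ± 0.32, AT4G01870 by 4.35 ± 0.34 and AT2G41730 by 4.15 ± 0.21. The CC-type glutaredoxin genes AT4G15680 (−1.65 ± 0.37) and AT4G15700 (−1.42 ± 0.24) fell. AT5G52390 fell (−2.27 ± 0.54), as did AT5G55420 (−1.59 ± 0.44) and the Yippee-type protein gene AT3G55890 (−1.59 ± 0.38). The unlisted probe set 263231_at had the largest rise, 6.60 ± 0.26.

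Among the 5 oxidative stress markers at day 2 of short days, 4 rose in cat2: GSTU25 by 3.53, WRKY6 by 2.43, STZ by 1.43 and AT2G21640 by 1.31 (list adjusted p = 1.18e-07, 0.00564 with an estimated correlation). Adjusted over the list alone all 5 rose. In the heat shock response list 2 of 3 rose, AT2G29500 and AT5G48570 (3.58), and ATHSP22.0 was not called (list adjusted p = 0.000239). Of 21 small heat shock proteins and co-chaperones, 9 rose and none fell, among them Fes1A (3.40), Hop3 (2.98) and AT1G53540 (2.67), with a list adjusted p of 2.65e-13. Of 47 UDP-glycosyltransferases, 11 rose, led by UGT73B1 (4.05), UGT73B5 (3.48), UGT73C1 (2.76) and UGT74D1 (2.31). A pair of them, UGT72B3 (−0.61) and UGT71B1 (−0.42), fell. The median of that family was −0.01 and its mean 0.36, and its test was Up (adjusted p = 0.0349, and adjusted p = 0.443 with an estimated correlation).

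Of 14 glutathione transferases 3 rose in cat2 at day 2 of short days, GSTU25, GSTU22 (1.06) and GSTU16 (0.76), with a list adjusted p of 0.0374 (adjusted p = 0.473 with an estimated correlation). The calcium sensor genes CML37 and CML38 rose by 2.38 and 1.49. In the sugar starvation list 2 of 4 rose, AT3G15450 (1.14) and IVD (0.67), with a list adjusted p of 0.00277, and 4 rose adjusted over the list alone. In sulfur assimilation only AT1G04770, known as SDI2 and induced by sulfur shortage, rose, by 1.36 (list adjusted p = 0.017, and adjusted p = 0.121 with an estimated correlation). Photorespiration gave a single rise among 6 genes, HPR (0.40). Of 7 antioxidant enzyme genes ATMDAR2 rose by 0.66 and GR1 by 0.52, whereas SAPX fell by 0.45. In all, 1505 probe sets rose and 1720 fell, and with each array centred on its median 34.7% of the calls were rises in place of 46.7%. Without Col-0 replicate 2 the count fell from 3225 to 1878, without cat2 replicate 1 to 1707 and without cat2 replicate 2 to 1812. It was 2041 with the BioB spike-in as a covariate and 1897 with the 25S ribosomal RNA control as a covariate.

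By day 4 of short days fewer probe sets were called between the genotypes, with fewer heat shock and glycosyltransferase genes among them. AT1G10585 rose by 4.73 ± 0.40 (adjusted p = 1.75e-08, limma with Benjamini-Hochberg), AT5G51440 by 4.67 ± 0.18, AT4G01870 by 4.12 ± 0.34, UGT73B1 by 4.00 ± 0.17 and AT5G16980, which codes for a zinc-binding dehydrogenase, by 3.91 ± 0.32. The named falls were AT3G55890 (−1.67 ± 0.38), the pectin methylesterase gene ATPMEPCRB (−1.53 ± 0.27), AT1G80130 (−1.43 ± 0.28), the lipid transfer protein gene AT5G55450 (−1.21 ± 0.27) and AT1G11700 (−0.84 ± 0.16). The unlisted probe set 256589_at rose by 6.01 ± 0.36. Oxidative stress markers rose for 2 of 5, WRKY6 (1.37) and AT2G21640 (1.00), with a list adjusted p of 1.44e-06, and 3 rose adjusted over the list alone. In the heat shock response list AT2G29500 alone rose (3.08; list adjusted p = 0.00248, 0.0278 with an estimated correlation).

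Of the 21 small heat shock proteins and co-chaperones 4 rose at day 4 of short days, among them Fes1A (2.05) and AT2G20560 (0.97), and of the 47 UDP-glycosyltransferases 6 rose and none fell, among them UGT74D1 (2.37), UGT84A3 (1.28) and UGT76E11 (1.13). The list adjusted p was 2.32e-07 and 2.89e-06. The 4 anthocyanin genes had a median of −1.39 with none called, although all 4 fell adjusted over the list alone (list adjusted p = 0.000372, and adjusted p = 0.147 with an estimated correlation). Lists without a called gene were sulfur assimilation (median 0.33, adjusted p = 0.02, and adjusted p = 0.147 with an estimated correlation) and starch synthesis (−0.48; 0.0412, 0.223). Endoplasmic reticulum protein folding (−0.18; 6.88e-05, 0.536) and flavonoid glycosylation (−0.77; 0.00103, 0.522) also had none. In all 347 probe sets rose and 37 fell, but with a replicate block and only these 6 arrays, a choice made after the values had been seen, 517 rose and 376 fell. The low count of falls thus depends on the fit. The residuals of these arrays correlated by replicate number, but whether equal numbers mark paired samples is not known. Both kinds of array weights raised the count. With the 25S control as a covariate 199 were called in place of 384, with all 384 signs kept and 93.3% of the median size left. The median standard error went from 0.16 to 0.20. The rises were shared across days, with 288 probe sets up on both days where 23 were expected by chance, and the log2 differences of the days had a correlation of 0.61 ± 0.22 (jackknife standard error), or 0.23 by Spearman.

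After 2 days of air in long days fewer genes were called between the genotypes. AT3G55920 rose by 3.03 ± 0.15 (adjusted p = 1.19e-12, limma with Benjamini-Hochberg), AT1G60590, a pectin lyase-like gene, by 2.31 ± 0.53, AT5G16980 by 2.30 ± 0.32, AT1G10585 by 2.29 ± 0.40 and AT5G47330, which codes for an alpha/beta hydrolase, by 2.29 ± 0.25. The jacalin lectin gene JAL23 fell (−1.86 ± 0.41), as did AT3G55890 (−1.83 ± 0.38), the cysteine protease gene AT3G49340 (−1.67 ± 0.40), AT3G48650 (−1.62 ± 0.36) and AT3G28220 (−1.59 ± 0.35). JAL23 lost its call whichever of the 6 arrays compared was left out. The unlisted probe set 245275_at fell (−4.47 ± 0.52). Within the small heat shock list AT2G29500 (1.60) and AT4G21870 (1.13) rose, and AT3G09440 (−0.60) and Hsp70-2 (−1.54) fell.

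Lists that moved at day 2 of long days did so by small shifts, and none kept its call with an estimated correlation. Endoplasmic reticulum protein folding had 1 of 18 called, Hsp70-2 (adjusted p = 0.214 with an estimated correlation). Immune receptors and defence signalling had 1 of 21, AT5G55450 at −1.32 (adjusted p = 0.195 with an estimated correlation). The jasmonate related list had 1 of 17, JAL23 (adjusted p = 0.0828 with an estimated correlation). Hsp70-2 was also in the small heat shock list, and JAL23 is a jacalin lectin gene that was listed by its symbol. These calls are thus no evidence on the endoplasmic reticulum or on jasmonate. Beta-glucosidases (median −0.12, adjusted p = 0.00718) and plastid-encoded photosynthesis genes (−0.06, adjusted p = 0.0282) had none called, with adjusted p = 0.0828 and adjusted p = 0.775 with an estimated correlation. In all 123 probe sets rose and 138 fell. The count of 261 fell to 89 without Col-0 replicate 1 and to 141 without Col-0 replicate 2, and to 97, 150 and 164 without cat2 replicates 1, 2 and 3. It was 611 with BioB and 132 with the 25S control as a covariate.

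By day 4 of long days COR15A was among the genes that fell in the mutant (−1.69 ± 0.21, adjusted p = 7.41e-05, limma with Benjamini-Hochberg). QQS, a gene that affects leaf starch, fell (−1.63 ± 0.18), as did AT3G55890 (−1.90 ± 0.38), the glutaredoxin gene AT5G11930 (−1.64 ± 0.36) and AT1G80130 (−1.27 ± 0.28). AT3G55920 rose by 3.40 ± 0.15, AT1G60590 by 2.66 ± 0.53, AT5G47330 by 2.16 ± 0.25, AT4G01870 by 1.56 ± 0.34 and AT3G20340 by 1.54 ± 0.24. In the abscisic acid and dehydration list (median −0.84) COR15A alone of 3 was called in the full test (list adjusted p = 1.66e-05, 0.0282 with an estimated correlation), and all 3 fell adjusted over the list alone. ATG8 autophagy (median −0.20, adjusted p = 0.0212) and endoplasmic reticulum protein folding (−0.18, 0.00116) had no member called, each with adjusted p = 0.736 with an estimated correlation. The 56 rises and 109 falls changed from 165 in all to 73 and 307 without Col-0 replicates 1 and 2, and to 259, 59 and 65 without cat2 replicates 1, 2 and 3. With BioB as a covariate 95 were called and with the 25S control 23. With only these 6 arrays 22 were called, and 238 with a replicate block as well. Between day 2 and day 4 of long days 29 probe sets rose on both, where 0.303 were expected by chance.

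The move to air itself acted differently on the genotypes at day 2 of short days. The interaction of genotype and air was 6.11 ± 0.25 for AT5G51440 (adjusted p = 8.74e-14, limma with Benjamini-Hochberg), 4.85 ± 0.62 for AT4G39670, which codes for a glycolipid transfer protein, 4.74 ± 0.57 for AT1G10585 and 4.51 ± 0.45 for AT2G29500. It was negative for the glutaredoxin genes AT4G15660 (−1.69 ± 0.34), AT4G15700 (−1.67 ± 0.34) and AT4G15690 (−1.52 ± 0.35) and for AT3G51750 (−1.49 ± 0.22). All 5 oxidative stress markers were positive, from NDB2 at 1.21 to GSTU25 at 3.43 (list adjusted p = 1.83e-09), as were 2 of 3 heat shock response genes (2.56e-05) and 7 of 21 small heat shock proteins and co-chaperones (8.72e-12). UDP-glycosyltransferases were positive for 7 and negative for UGT72B3 (list adjusted p = 0.00107, and adjusted p = 0.102 with an estimated correlation). Immune receptor genes were positive for BIK1 (1.23) and WRKY6 (list adjusted p = 0.00516, and adjusted p = 0.438 with an estimated correlation), and SDI2 for sulfur assimilation (1.60; adjusted p = 0.00664, and adjusted p = 0.0649 with an estimated correlation). Sugar starvation had no gene called (0.0364, 0.0649). In all 649 interactions were positive and 717 negative. Leaving out single arrays gave 834 (cat2 hCO2 replicate 2) to 2119 (cat2 hCO2 replicate 3). The count of 1366 was 616 with BioB and 745 with the actin difference as a covariate, 6282 with array weights and 4141 with weights estimated gene by gene.

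At day 4 of short days fewer interactions were called, with AT5G51440 at 4.79 ± 0.25 (adjusted p = 2.1e-11, limma with Benjamini-Hochberg), AT1G10585 at 4.57 ± 0.57, AT4G01870 at 4.02 ± 0.48 and AT5G16980 at 3.89 ± 0.46. It was negative for AT5G57760 (−1.48 ± 0.27), AT2G48030 (−0.87 ± 0.17), the RING-type gene AT3G47180 (−0.83 ± 0.19) and AT4G24970 (−0.82 ± 0.19). WRKY6 (1.70) was the only called oxidative stress marker, and 5 of 47 UDP-glycosyltransferases were positive, UGT73B1 at 3.62, UGT74D1 at 2.44, UGT73C1 at 2.21, UGT73B5 at 1.92 and UGT84A3 at 1.22 (list adjusted p = 6.01e-08, 0.00644 with an estimated correlation). The anthocyanin list was negative with a median of −2.11, none called in the full test and 4 adjusted over the list alone (list adjusted p = 2.73e-05, and adjusted p = 0.0789 with an estimated correlation). In all 188 were positive and 15 negative, a count of 203 that rose to 1671 with array weights and 560 with weights estimated gene by gene.

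For long days against CO2, which changes air and day length together, few interactions with genotype were called. At day 2 there were 25 positive and 17 negative, with AT5G16980 at 2.29 ± 0.46 (adjusted p = 0.032, limma with Benjamini-Hochberg), AT5G47330 at 2.05 ± 0.36, AT2G41730 at 1.66 ± 0.30 and AT5G61820 at 1.65 ± 0.32. The lectin gene AT5G03350 (−1.53 ± 0.29), AT1G19960 (−1.21 ± 0.26), AT1G74440 (−1.05 ± 0.19) and AT5G22390 (−1.01 ± 0.19) were negative. At day 4 there were 5 positive and 23 negative, with AT5G47330 (1.92 ± 0.36), AT1G75960 (1.4 ± 0.27) and the small heat shock gene AT4G21870 (1.31 ± 0.25) positive. COR15A (−1.98 ± 0.29), QQS (−1.98 ± 0.26), the MADS-box gene AGL19 (−1.42 ± 0.26) and AT3G51750 (−1.13 ± 0.22) were negative. The abscisic acid and dehydration list was negative at day 4 (median −1.39), with COR15A called in the full test and all 3 genes adjusted over the list alone (list adjusted p = 1.27e-07, 0.00626 with an estimated correlation). Unadjusted p was under 0.05 for 1255 probe sets at day 2 and 1621 at day 4. Leaving out single arrays gave 14 to 46 calls at day 2 and 5 to 73 at day 4. With array weights 894 and 222 were called at day 2 and day 4, with weights estimated gene by gene 211 and 47, and with only the arrays compared 13 and 2. At day 4 as many as the real count were called in 5 of 100 shuffles of the arrays.

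In Col-0, 2 days of air in short days raised cold and dehydration genes. AT4G28140, an AP2/ERF transcription factor gene, rose by 2.75 ± 0.26 (adjusted p = 7.71e-07, limma with Benjamini-Hochberg), AT5G15190 by 2.51 ± 0.41, AT1G71000, which codes for a DnaJ-domain protein, by 2.45 ± 0.31 and AT1G16850 by 2.35 ± 0.34. The acid phosphatase gene AT1G04040 fell (−2.27 ± 0.19), as did the coiled-coil protein genes AT5G41140 and AT5G16730 (−2.16 ± 0.37, −2.08 ± 0.52) and AT2G15042 (−1.86 ± 0.28). All 3 genes of the abscisic acid and dehydration list rose, LTI30 by 2.35, COR47 by 1.33 and COR15A by 0.94 (list adjusted p = 0.0017, and adjusted p = 0.15 with an estimated correlation), and all 3 rose adjusted over the list alone. Of 15 LEA and cold genes 6 rose, among them COR27 (1.41), COR15B (0.92) and XERICO (0.58), and none fell (list adjusted p = 0.00644, and adjusted p = 0.265 with an estimated correlation).

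Some genes of sulfur assimilation and of the TCA cycle list fell at the same time. In the sulfur list 2 of 4 genes fell, APS3 (−0.52) and SIR (−0.41), and 3 adjusted over the list alone (list adjusted p = 0.0202, and adjusted p = 0.185 with an estimated correlation). In the TCA cycle list 5 of 15 genes fell, among them ACLA-1 (−0.67), SDH1-1 (−0.59) and cICDH (−0.41). The list adjusted p was 0.0381 (adjusted p = 0.265 with an estimated correlation). That list was written from gene symbols, so its members, ACLA-1 and cICDH among them, need not be enzymes of the cycle itself. Of 9 ATG8 genes 3 rose, ATG8C (0.72), ATG8D (0.58) and ATG8H (0.47), with a list adjusted p of 0.0231 (adjusted p = 0.839 with an estimated correlation). SWEET4 rose by 1.60 and SWEET11, the phloem marker, fell (−0.68). In all 2156 probe sets rose and 2390 fell, and with each array centred on its median 64.8% of the calls were rises in place of 47.4%. The BioB spike-in averaged 8.27 ± 0.12 (standard deviation) in this group and 7.82 ± 0.12 at CO2, the actin 3' minus 5' difference 2.03 ± 0.10 and 2.24 ± 0.09, and with BioB as a covariate 701 probe sets were called. Without SD2 replicate 2 the count was 2657.

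By day 4 of short days Col-0 leaves had raised anthocyanin genes while the dehydration genes stayed up. HIS1-3, a drought-inducible linker histone gene, rose by 2.77 ± 0.40 (adjusted p = 0.000357, limma with Benjamini-Hochberg), AT2G23910 by 2.38 ± 0.25, AT4G14090, known as UGT75C1 and an anthocyanin glucosyltransferase, by 2.35 ± 0.57 and AT1G71000 by 2.19 ± 0.31. The chitinase gene AT2G43590 fell (−2.29 ± 0.48), as did the MATE transporter gene AT3G23550 (−2.2 ± 0.51), AT1G04040 (−1.99 ± 0.19) and AT5G40450 (−1.89 ± 0.30). Of 4 anthocyanin genes 3 rose, AT4G14090, UF3GT (2.15) and AT5MAT (1.45), and 4 adjusted over the list alone (list adjusted p = 5.78e-06, and adjusted p = 0.0592 with an estimated correlation). LTI30 (1.87), COR47 (1.02) and COR15A (0.81) rose again, all 3 of their list (list adjusted p = 1.29e-05, 0.0327 with an estimated correlation).

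Sulfur assimilation fell again at day 4 of short days, for 2 of 4 genes, APS3 (−0.75) and SIR (−0.50), with 2 adjusted over the list alone (list adjusted p = 0.000585, 0.0417 with an estimated correlation). Glucosinolate genes fell for 2 of 3, UGT74B1 (−0.55) and AT2G31790 (−0.46) (list adjusted p = 0.00106, and adjusted p = 0.0592 with an estimated correlation). Of 43 plastid-encoded photosynthesis genes only petG (1.29), petL (0.70) and psaJ (0.36) rose, with a list adjusted p of 8.01e-08 (adjusted p = 0.335 with an estimated correlation). LEA and cold genes rose for 5 of 15 (1.53e-05, and adjusted p = 0.0917 with an estimated correlation) and flavonoid glycosylation genes for 4 of 9 (1.89e-05, and adjusted p = 0.204 with an estimated correlation). The ATG8 list (median 0.32, list adjusted p = 0.00215, 0.527 with an estimated correlation) and the TCA cycle list (−0.14, 0.00883, 0.128) had none called. In all 356 probe sets rose and 225 fell. Leaving out hCO2 replicates 1, 2 and 3 gave 280, 306 and 305 calls in place of 581, and leaving out SD4 replicates 1, 2 and 3 gave 296, 333 and 240.

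After 2 days of air in long days 5 of 9 ATG8 autophagy genes rose in Col-0 and 3 of 15 LEA and cold genes fell. DFR, a gene of anthocyanin synthesis, rose by 2.84 ± 0.88 (adjusted p = 0.0386, limma with Benjamini-Hochberg), AT1G30250 by 2.03 ± 0.23, the lipid transfer protein gene AT2G37870 by 1.99 ± 0.43 and AT3G06070 by 1.85 ± 0.20. DFR lost its call whichever of the 6 arrays compared was left out, and the anthocyanin list was not called (list adjusted p = 0.0543, 0.448 with an estimated correlation). AT1G31690, which codes for a copper amine oxidase, fell on both of its probe sets (−3.56 ± 0.51, −3.34 ± 0.46). AT5G41140 fell (−2.41 ± 0.37), as did the aspartyl protease gene AT5G07030 (−2.17 ± 0.42). Of 9 ATG8 genes 5 rose, among them ATG8E (1.68), ATG8G (0.70) and ATG8F (0.67), with a list adjusted p of 0.000118 (adjusted p = 0.726 with an estimated correlation). COR15B fell (−1.07), as did COR15A (−1.02) and COR27 (−0.80), but neither the LEA and cold list (median 0.03, adjusted p = 0.2) nor the dehydration list (adjusted p = 0.0543) was called. AT3G15450, known as SEN5, rose by 1.36 and AKINBETA1 by 1.06. In all 1373 probe sets rose and 1236 fell. The count of 2609 fell to 1648 and 1173 without hCO2 replicates 1 and 2, and to 1341 and 1627 without LD2 replicates 1 and 3, and was 1653 with BioB as a covariate.

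By day 4 of long days the largest rise of a named gene in Col-0 was that of AT4G27450, which is of the same protein family as SEN5. It rose by 3.19 ± 0.45 (adjusted p = 3.11e-05, limma with Benjamini-Hochberg), AT5G57340 by 2.64 ± 0.21, AT3G15450 by 2.37 ± 0.22 and AT2G41250 by 2.13 ± 0.42, and the unlisted probe set 249467_at by 3.48 ± 0.48. AT1G31690 fell on both probe sets (−3.70 ± 0.51, −3.15 ± 0.46), as did the methyltransferase gene AT3G21950 (−2.1 ± 0.29) and ZW9 (−1.88 ± 0.46). In the sugar starvation list 2 of 4 rose, AT3G15450 and AKINBETA1 (1.46), and MCCB and IVD were not called (list adjusted p = 0.00219, 0.0135 with an estimated correlation). All 9 ATG8 genes rose, from ATG8D (0.63) to ATG8E (1.78), with a list adjusted p of 2.82e-07 (adjusted p = 0.339 with an estimated correlation). Of 5 photosynthetic light reaction genes LHCB4.3 rose by 0.84 and LHCB4.2 by 0.46 (list adjusted p = 0.0242, and adjusted p = 0.193 with an estimated correlation). COR27 fell (−1.34), as did COR15A (−1.04) and COR15B (−0.51). In all 2061 probe sets rose and 1655 fell, and the count of 3716 fell to 2314 without hCO2 replicate 2 and to 2293 without LD4 replicate 1.

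Within a day length many changes of Col-0 were shared between the days, with 902 probe sets up and 702 down on both days of long days, where 124 and 89.9 were expected by chance. In short days 329 rose and 192 fell on both days (34 and 24 by chance). Across day lengths at day 2, 484 rose and 631 fell in both (130 and 130 by chance), and 118 moved in opposite directions. All 4 comparisons used the same 3 CO2 arrays. The correlations of 0.83 (within short days), 0.76 (within long days) and 0.48 (across day lengths at day 2) thus stand beside a simulated value of 0.5 for groups without change. Their covariances were 0.077, 0.0872 and 0.0586 against a simulated 0.0121, so more was shared than independent noise in the CO2 arrays gives. Noise shared between genes, or a technical shift common to the CO2 arrays, was not simulated and could add to what was shared. The numbers expected by chance take the comparisons as independent, which they were not.

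Long days lowered cold and dehydration genes in both genotypes. In Col-0 at day 2, ZW9 was lower in long days (−3.09 ± 0.46, adjusted p = 5.11e-05, limma with Benjamini-Hochberg), as were AT1G71000 (−3.74 ± 0.31) and AT1G31690 (−3.32 ± 0.51, −3.28 ± 0.46). The hydrolase gene AT2G41250 was higher by 2.58 ± 0.42, AT1G13650 by 2.56 ± 0.44, AT1G43910 by 2.28 ± 0.43 and AT3G23550 by 2.13 ± 0.51. All 3 abscisic acid and dehydration genes fell, LTI30 (−2.60), COR15A (−1.96) and COR47 (−1.88) (list adjusted p = 5.55e-07, 0.00965 with an estimated correlation), as did 6 of 15 LEA and cold genes (6.97e-05, and adjusted p = 0.0793 with an estimated correlation). Sulfur assimilation rose for 3 of 4, AT1G04770 by 0.97, APS3 by 0.82 and SIR by 0.45 (0.000632, 0.0241 with an estimated correlation), and sugar starvation for 2 of 4, AT3G15450 by 1.17 and AKINBETA1 by 0.76 (0.00648, 0.0241 with an estimated correlation). In the TCA cycle list, written from gene symbols, 7 of 15 genes rose and ACLA-2 fell (0.0175, and adjusted p = 0.0793 with an estimated correlation). In all 1387 probe sets were higher and 1289 lower in long days, 41.3% higher in place of 51.8% with each array centred on its median, and 1606 were called without LD2 replicate 1.

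At day 4 long days also lowered anthocyanin genes in Col-0. All 4 fell, DFR (−3.34 ± 0.88, adjusted p = 0.0116, limma with Benjamini-Hochberg), AT4G14090 (−2.65), UF3GT (−2.51) and AT5MAT (−1.26) (list adjusted p = 0.000246, and adjusted p = 0.133 with an estimated correlation). AT1G31690 fell (−3.72 ± 0.51, −3.31 ± 0.46), as did AT1G71000 (−3.36 ± 0.31). AT2G41250 rose by 2.75 ± 0.42, AT4G27450 by 2.75 ± 0.45, AT3G15450 by 2.34 ± 0.22 and AT4G22490 by 2.25 ± 0.18. COR27 fell (−2.49), as did LTI30 (−2.29) and COR15A (−1.84), and all 3 genes of the abscisic acid list fell (4.45e-05, 0.0197 with an estimated correlation). Sugar starvation rose for 2 of 4 (0.000419, 0.00976 with an estimated correlation), and sulfur assimilation for 2 of 4 (0.0155, and adjusted p = 0.133 with an estimated correlation). ATG8 genes rose for 4 of 9 (0.000793, and adjusted p = 0.504 with an estimated correlation), CYP71B genes for 4 of 19, led by CYP71B22 at 1.87 (0.00821, and adjusted p = 0.116 with an estimated correlation), and plastid-encoded genes fell for 7 of 43 (1.81e-06, and adjusted p = 0.463 with an estimated correlation). In all 1618 probe sets were higher and 1444 lower in long days, and 2013 were called without SD4 replicate 3.

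In cat2 at day 2 long days held down the heat shock program. AT1G71000 was lower in long days (−6.26 ± 0.31, adjusted p = 7.83e-13, limma with Benjamini-Hochberg), as were AT5G51440 (−6.05 ± 0.18), AT5G48570 (−4.22 ± 0.40) and Fes1A (−3.78 ± 0.17). The lipid transfer protein genes AT4G12490 and AT4G12500 were higher by 4.99 ± 0.78 and 3.66 ± 0.64, AT1G26390 by 2.2 ± 0.61 and AT2G16660 by 2.2 ± 0.16. Of 21 small heat shock proteins and co-chaperones 11 fell and AT4G21870 rose by 1.80 (list adjusted p = 1.31e-09, 0.00313 with an estimated correlation). Oxidative stress markers fell for 3 of 5, GSTU25 (−2.58), STZ (−2.52) and WRKY6 (−2.26) (list adjusted p = 3.88e-06, 0.0078 with an estimated correlation), and all 3 dehydration genes fell (4.73e-06, 0.0078 with an estimated correlation). UDP-glycosyltransferases fell for 11 and rose for 4 of 47 (0.00696, and adjusted p = 0.189 with an estimated correlation), and glutathione transferases fell for 5 of 14 (0.00958, and adjusted p = 0.199 with an estimated correlation). LEA and cold genes fell for 8 of 15 (4.39e-06, 0.0329 with an estimated correlation). In all 1993 probe sets were higher and 1675 lower in long days, and 2281 were called without SD2 replicate 1.

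At day 4 in cat2 AT1G71000 was lower in long days (−5.88 ± 0.31, adjusted p = 5.75e-12, limma with Benjamini-Hochberg), as were AT5G51440 (−4.85 ± 0.18), AT1G10585 (−3.77 ± 0.40) and AT5G16980 (−3.76 ± 0.32). The glucanase gene AT4G16260 was higher by 4.2 ± 0.84, AT4G12490 by 3.61 ± 0.78, AT3G23550 by 2.82 ± 0.51 and the lipid transfer protein gene AT5G48490 by 2.61 ± 0.59. COR15A was lower (−3.54), as were LTI30 (−3.09) and COR47 (−2.18), all 3 of the dehydration list (2.94e-09, 0.00224 with an estimated correlation). Of the small heat shock list 7 fell and 2 rose, AT4G21870 (1.73) and Fes1C (0.51), with a list adjusted p of 0.000892 (adjusted p = 0.13 with an estimated correlation). Sugar starvation rose for 2 of 4, AT3G15450 by 2.14 and AKINBETA1 by 1.07 (0.00292, 0.0123 with an estimated correlation). UDP-glycosyltransferases fell for 13 and rose for 4 of 47 (0.0142, and adjusted p = 0.269 with an estimated correlation). In all 1254 probe sets were higher and 1422 lower in long days.

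At day 2 heat shock and oxidative stress genes were among the negative interactions of genotype and day length. The interaction was −6.68 ± 0.71 for the unlisted probe set 248332_at. It was −5.93 ± 0.25 for AT5G51440 (adjusted p = 1.71e-13, limma with Benjamini-Hochberg), −4.67 ± 0.62 for AT4G39670, −4.58 ± 0.57 for AT5G48570 and −3.77 ± 0.28 for AT3G22060. It was positive for AT1G23100 (1.76 ± 0.27), AT3G61100 (1.65 ± 0.40), the ribosomal protein gene AT2G32220 (1.62 ± 0.34) and AT3G59670 (1.61 ± 0.40). Of the small heat shock list 10 were negative and AT4G21870 was positive at 0.83 (list adjusted p = 1.89e-11, 0.00116 with an estimated correlation). Oxidative stress markers were negative for 3 of 5, GSTU25 at −2.57, STZ at −2.55 and WRKY6 at −2.42 (9.7e-06, 0.0122 with an estimated correlation). Sugar starvation was negative with none called, and with 4 adjusted over the list alone (0.00823, 0.0212 with an estimated correlation). Beta-glucosidases were negative for 3 of 20, BGLU33 (−1.52), BGLU47 (−1.31) and BGLU16 (−0.63), with a list adjusted p of 0.0102 (adjusted p = 0.0697 with an estimated correlation). In all 940 were positive and 815 negative. Without single arrays the count of 1755 fell to 1164 (Col-0 SD2 replicate 2), 939 (Col-0 LD2 replicate 1), 994 and 1099 (cat2 SD2 replicates 1 and 2) and 1069 (cat2 LD2 replicate 2), and it was 1036 with the actin difference as a covariate.

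At day 4 the interaction of genotype and day length was negative for AT1G10585 (−4.82 ± 0.57, adjusted p = 1.67e-05, limma with Benjamini-Hochberg), AT5G51440 (−4.66 ± 0.25), AT1G09500 (−3.38 ± 0.60) and AT5G16980 (−3.38 ± 0.46). It was positive for ATPMEPCRB (1.92 ± 0.38), AT4G02930, which codes for an elongation factor Tu (0.92 ± 0.20), AT5G14580 (0.84 ± 0.17) and AT3G49320 (0.79 ± 0.19). COR15A was negative (−1.70), the only called gene of the abscisic acid list (list adjusted p = 0.00011, and adjusted p = 0.0539 with an estimated correlation). UGT73B1 (−2.79), UGT73C1 (−1.98) and UGT74D1 (−1.73) were negative among 47 UDP-glycosyltransferases (0.00213, and adjusted p = 0.147 with an estimated correlation). In all 11 were positive and 185 negative.

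Between day 2 and day 4 the heat shock program of cat2 declined in short days. CML37 fell (−2.49 ± 0.27, adjusted p = 8.39e-06, limma with Benjamini-Hochberg), as did AT1G05575 (−2.35 ± 0.35), GSTU25 (−2.16), Hop3 (−2.03) and UGT73B5 (−1.84), while AT4G10270 rose by 1.23 ± 0.29 and AT5G47330 by 1.06 ± 0.25. The call of AT5G47330 was lost whichever of the 6 arrays compared was left out. Small heat shock proteins and co-chaperones fell for 6 of 21 (list adjusted p = 1.34e-13, 0.000405 with an estimated correlation), oxidative stress markers for 3 of 5 (3.76e-11, 0.000695 with an estimated correlation), heat shock response genes for 2 of 3 (3.81e-05, 0.00262 with an estimated correlation) and calmodulin-like genes for 2 of 7 (0.000138, 0.0376 with an estimated correlation). UDP-glycosyltransferases fell for 2 of 47, and their list was not called (list adjusted p = 0.0826, 0.413 with an estimated correlation). In all 39 probe sets rose and 177 fell. The count of 216 fell to 103 and 106 without SD2 replicates 1 and 2 and to 93 and 137 without SD4 replicates 2 and 3.

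Between the days of short days few probe sets were called in Col-0, with falls of AT4G28140 (−1.5 ± 0.26, adjusted p = 0.027, limma with Benjamini-Hochberg) and AT5G53710 (−1.30 ± 0.22). There were 11 calls there, 2872 probe sets had an unadjusted p under 0.05, and leaving out SD2 replicate 1 gave 18 and SD4 replicate 2 gave 1. With array weights 567 were called there, and 494 with weights estimated gene by gene. In long days AT5G62280 rose in Col-0 by 1.58 ± 0.25, AT5G50335 by 1.5 ± 0.28 and AT3G15450 by 1.01, and the growth gene EXO fell (−1.56 ± 0.27), as did AT2G32190 (−1.45 ± 0.21) and EXLA1 (−1.09). There 242 probe sets rose and 200 fell, and the count of 442 fell to 195, 158 and 215 without LD2 replicates 1, 2 and 3. In cat2 the zinc finger gene STZ rose by 1.44 ± 0.33 in long days and AT4G24350 by 1.35 ± 0.29, whereas AT2G37870 fell (−2.0 ± 0.43), as did AT2G41730 (−1.85 ± 0.21), LTI30 (−1.78) and COR15A (−1.48). There 137 probe sets rose and 250 fell, and the count of 387 fell to 160 and 104 without LD2 replicates 2 and 3 and to 79 without LD4 replicate 2. The anthocyanin list shifted up in Col-0 short days (median 1.31, adjusted p = 0.00183, and adjusted p = 0.451 with an estimated correlation) and down in Col-0 long days (−1.81; 0.000724, 0.292) with no gene called.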

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

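The tests of technical explanations were chosen only after the result had been seen, and counts with the BioB and actin covariates had been looked at for all comparisons. The test of single SD4 arrays and the splits of the arrays were set before their results were seen, and the shuffles for interactions after the splits had been seen.

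The interaction of genotype and air was called for 1366 probe sets at SD2, with AT5G51440 at 6.11, AT4G39670 at 4.85, AT4G15660 at −1.69 and AT4G15700 at −1.67. At SD4 it was called for 203, with AT5G51440 at 4.79, AT1G10585 at 4.57, AT5G57760 at −1.48 and AT2G48030 at −0.87. For long days the comparison with CO2 changes air and day length together. At LD2 it was called for 42, with AT5G16980 at 2.29, AT5G47330 at 2.05, AT5G03350 at −1.53 and AT1G19960 at −1.21. At LD4 it was called for 28, with AT5G47330 at 1.92, AT1G75960 at 1.4, COR15A at −1.98 and QQS at −1.98. The interaction of genotype and day length was called for 1755 at day 2, with AT1G23100 at 1.76, AT3G61100 at 1.65, AT5G51440 at −5.93 and AT4G39670 at −4.67. At day 4 it was called for 196, with ATPMEPCRB at 1.92, AT4G02930 at 0.92, AT1G10585 at −4.82 and AT5G51440 at −4.66.

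AT3G55920 was higher in cat2 in all 5 conditions, and AT3G55890 was lower in all 5, with a call in the 4 in air (adjusted p = 0.113 at CO2). For AT3G55920 0 cat2 arrays lay at or below the highest Col-0 array, which decides nothing on a mislabelled sample, as the gene was picked for this difference. A need for the move to air was tested with a choice of genes that uses no CO2 array, made after the CO2 values had been seen. Among the 19 probe sets called with the same sign in all 4 air conditions, AT3G55890 differed at CO2 (−1.81 ± 0.38, adjusted p = 0.000301 over the 19), as did AT3G55920 (4.04 ± 0.15). AT3G55920 was also called at CO2 over all probe sets (adjusted p = 3.55e-15, limma with Benjamini-Hochberg), which excludes such a need for this gene. For AT3G55890 the values argue against such a need but rest on that late choice and that shared spread. A change of the chromosome neighbourhood stays open, since these genes lie on the same chromosome with 2 loci between them and only 9 of the 22 other genes within 10 loci on either side were measured. Of those 9, 0 differed by over 0.5 on average, and AT3G55840 was called in 1 condition (0.70 at SD2). A difference between the lines in how the probes bind was not tested and stays open.

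At day 2 the genotypes differed at 3225 probe sets in short days and 261 in long days. A larger spread between arrays in long days was not seen, since the mean standard deviation at LD2 was 0.96 times that at SD2. The fit shared a single estimate of the spread per probe set among all groups. This ratio thus does not bear on the standard errors behind the counts. With the BioB spike-in as a covariate 96.6% of the median size of the interactions of genotype and day length was left. With BioB the counts for genotype became 2041 and 611, so part of the gap between them went with it. With the actin controls as a covariate 89.7% of the median size of the interactions was left and all 1755 signs were kept. The median size went from 0.81 to 0.73 and its standard error from 0.20 to 0.19, and the count from 1755 to 1036. What ended these calls was not tested. The count of calls was the measure chosen first, and by it the actin controls had been left open. The median size was chosen later, and a covariate takes out only what its control follows. The sizes left argue against array hybridization or transcript coverage as the whole cause, but neither was excluded.

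In Col-0, air called 4546 probe sets at SD2 and 581 at SD4, although a direct comparison of these groups called 11. Array hybridization followed by the BioB spike-in stays open, since 73.4% of the median size of the SD2 changes was left with it as a covariate. The median size went from 0.53 to 0.39 and its standard error from 0.14 to 0.17. With the actin controls as a covariate 87.9% of the median size of the SD2 changes was left. This argues against transcript coverage as the whole cause but does not exclude it. A single deviating SD4 array stays open. Leaving out any of the SD4 arrays gave at most 333 calls, so no rise towards the SD2 count was seen. However, leaving out any of the 6 arrays compared lowered the count, to between 240 and 333, so a loss of calls came with fewer arrays. Both kinds of array weights raised the SD4 count.

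Splits of the arrays into other groupings gave a further check. For comparisons of a pair of groups there were 10 splits, too few for a share under 0.05, and only the real split reached the real count except at CO2. For air in Col-0 the real counts were 4546, 581, 2609 and 3716 at SD2, SD4, LD2 and LD4, and the highest of the other splits 0, 0, 1 and 0. For genotype the real counts were 3, 3225, 384, 261 and 165 at hCO2, SD2, SD4, LD2 and LD4, and the highest of the others 3134, 4, 1, 0 and 113. At hCO2 thus 2 splits reached 3 calls, and the split with 3134 put cat2 replicate 3 with Col-0 replicates 1 and 3, which points to structure of the samples within the groups. For day length the real counts were 2676 and 3062 in Col-0 and 3668 and 2676 in cat2, with 1, 363, 1 and 1 as the highest of the others. For time they were 11 and 442 in Col-0 and 216 and 387 in cat2, with 0, 2, 11 and 1.

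For interactions splits of the 12 arrays also mix the main effects of genotype and condition, so they were set aside (the real count was reached by 8, 9, 7 and 21 of 100 at SD2, SD4, LD2 and LD4, and by 1 and 8 for day length at day 2 and day 4). The main effects were kept instead, and what they left was shuffled among the arrays 99 times, the real arrays being counted as the last of 100. The counts of 1366 at SD2, 203 at SD4 and 42 at LD2 and that of 1755 for day length at day 2 were reached only by the real arrays (highest of the others 964, 93, 0 and 435), and that of 196 for day length at day 4 by 3 (highest 1402). An arbitrary grouping of the arrays was thus made less likely for these but was not excluded. The shuffles were chosen after the splits had been seen and were not adjusted over the interactions. They also ignored the correlation of residuals by replicate number between cat2 and Col-0 arrays at SD4 and LD4. The count of 28 at LD4 was reached by 5 (highest 1970), and there the shuffles did not speak against an arbitrary grouping.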

How the results depend on the processing

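List tests after another scaling, the covariate fits, the array weights estimated gene by gene and the replicate block in a fit of only the arrays compared were chosen after the data had been seen, and all other settings before. No named gene turned its direction under any setting, and no called list under those run for lists. Of 167 named values, 165 kept their call with a replicate block, 124 with only the arrays compared, 163 with quantile normalization, 162 with centring, 166 with trend and robust options and 163 with array weights (162 gene by gene). With BioB as a covariate 144 kept it, with the actin difference 166 and with the 25S control 141. With the filter all 160 of those left kept it, with 1 probe set per gene 162 of 163, and with single arrays left out 1044 of 1284. Of 146 called lists 45 kept the call with an estimated correlation, 145 with the block, 138 with quantile normalization, 143 with centring, 144 with the mean of the probe sets of a gene, 108 of 137 with the filter and 356 of 438 with single replicates left out. Where no cause is given, the cause was not tested.

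All 23 counts stayed within 1.5 times with the replicate block (for example 4587 for air in Col-0 at SD2, 3170 for genotype at SD2 and 393 at SD4), as they did with the filter and with trend and robust options. The block together with only the arrays compared, run for genotype at SD4 and LD4 alone, gave 893 in place of 384 and 238 in place of 165. With only the arrays compared, which leaves fewer arrays to estimate the spread, air in Col-0 gave 172 at SD4 and 1172 at LD4, genotype 22 at LD4, the interaction with air 13 at LD2 and 2 at LD4, long days 1314 in Col-0 at day 4, the interaction with day length 2796 at day 2, and time 0 (Col-0) and 124 (cat2) in short days and 26 and 17 in long days. Quantile normalization gave 11 for the interaction at LD4, and centring 14 there and 18 for time in Col-0 short days.

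Array weights gave cat2 hCO2 replicate 1 a weight of 25.9 and their estimation did not converge. With them air in Col-0 gave 7013 at SD2, 2195 at SD4 and 5460 at LD2, genotype 7694 at hCO2, 1290 at SD4, 663 at LD2 and 50 at LD4, and the interaction with air 6282, 1671, 894 and 222 at SD2, SD4, LD2 and LD4. Day length gave 4146 for Col-0 at day 2, 4222 for cat2 at day 4 and 2745 for its interaction at day 2, and time 567 and 510 in short days and 194 and 1400 in long days for Col-0 and cat2. Weights estimated gene by gene, tried because of that failure, gave 1532 at SD4 and 4476 at LD2 for air in Col-0, 1847, 1177, 632 and 48 for genotype at hCO2, SD4, LD2 and LD4, and 4141, 560, 211 and 47 for the interaction with air. Day length gave 4064 for Col-0 at day 2, 4152 for cat2 at day 4 and 2730 for its interaction at day 2, and time 494 and 504 in short days and 172 and 1338 in long days.

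With 1 probe set per single gene, which tests fewer probe sets by construction, air in Col-0 gave 2424, 298, 1387 and 2003 at SD2, SD4, LD2 and LD4, genotype 1722, 163, 113 and 75, and the interaction with air 723, 86, 19 and 11. Day length gave 1318 and 1572 in Col-0 and 1884 and 1272 in cat2 at day 2 and day 4, its interaction 896 and 80, and time 2 and 114 in short days and 204 and 190 in long days.

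With BioB as a covariate air in Col-0 gave 701 at SD2, 282 at SD4 and 1653 at LD2, genotype 2041 at SD2, 611 at LD2 and 95 at LD4, the interaction with air 616 at SD2 and time 213 in Col-0 long days. With the actin difference the interaction with air gave 745 at SD2 and 49 at LD4, that with day length at day 2 gave 1036, and time 759 in cat2 long days. With the 25S control, whose mean was higher in cat2 in air without a call, genotype gave 1897, 199, 132 and 23 at SD2, SD4, LD2 and LD4. There 97.4%, 93.3%, 100% and 92.6% of the median size of the genotype calls was left, with all signs kept. The interaction with air gave 25 at LD2 and 7 at LD4. Of the 4546 calls for Col-0 at SD2, 638 were called with BioB and 3166 with actin, and 4544 and 4546 kept their sign.

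With single arrays left out the counts ranged as follows. Air in Col-0 gave 2657 to 3775 at SD2, 240 to 333 at SD4, 1173 to 2401 at LD2 and 2293 to 4137 at LD4. Genotype gave 2 to 70 at hCO2, 1707 to 2864 at SD2, 89 to 282 at LD2 and 59 to 307 at LD4. The interaction with air gave 834 to 2119 at SD2, 14 to 46 at LD2 and 5 to 73 at LD4. Day length gave 1606 to 2196 and 2013 to 3297 in Col-0 at day 2 and day 4, 2281 to 3429 in cat2 at day 2, and 939 to 1738 for its interaction at day 2. Time gave 1 to 18 and 93 to 229 in short days and 158 to 541 and 79 to 305 in long days for Col-0 and cat2. Genotype at SD4 (272 to 348), its interaction with air (147 to 270), day length in cat2 at day 4 (1954 to 2246) and its interaction (132 to 274) stayed within 1.5 times.

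By Spearman correlation the genotype differences at hCO2 and SD2 gave −0.03 in place of 0.02 and those at SD2 and LD2 −0.05 in place of 0.15, a turn of sign. Those at SD2 and SD4 gave 0.23 in place of 0.61 and those at SD4 and LD2 0.27 in place of 0.45.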

Other observations

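The lists of observed groups below and the table of persistent genes were chosen only after the results had been seen, apart from the lists fixed before.

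Some genes differed between the genotypes in every air condition, whatever the day length. With the same sign in all 4 there were 19 probe sets, 11 of them with exactly 1 gene. Among these AT5G47330 rose by 1.54, 2.89, 2.29 and 2.16 at SD2, SD4, LD2 and LD4, OCT5, an organic cation transporter gene, by 2.25, 2.81, 1.64 and 0.86, AT3G20340 by 2.38, 2.49, 1.34 and 1.54 and UGT73B1 by 4.05, 4.00, 1.57 and 1.2. AT1G57590, AT5G02480, AT3G62860, AT4G01870 and AT1G43590 rose as well. AT3G55920 and the probe set 253174_at were the only ones called in all 5 conditions.

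The lists of SWEET and of cell wall expansion genes were not called in any comparison. SWEET4 was lower in long days at day 2 and day 4 (−1.45 and −1.67 in Col-0, −1.13 and −1.74 in cat2), and SWEET2 was higher by 1.06 in Col-0 at day 4 and 1.18 in cat2 at day 2. Of 14 SWEET genes 5 were called in any comparison. Of 27 cell wall expansion genes 12 were, with EXPB3 lower (−1.49) and XTH19 higher (1.16) in Col-0 long days at day 4. Of 29 SCPL genes 9 were called in any comparison, with scpl20 lower in cat2 long days at day 4 (−1.06), and of 11 tetrapyrrole genes 5, with PORB lower in Col-0 at SD2 (−0.64). The tetrapyrrole and SCPL lists were never called.

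Among the fixed lists, photorespiration was not called in any comparison, with 2 of 6 genes called in any, HPR and AT1G11860. Jasmonate had 3 genes and none called. Starch synthesis had 3 genes, of which SBE2.2 fell in Col-0 at SD2 (−0.60). Lists with fewer than 3 measured genes were not tested. The clock gene GI fell in Col-0 at SD2 (−0.55), LD2 (−0.77) and LD4 (−0.73), the guard cell gene FMA (FAMA) fell there at SD2 (−0.46), and GRX480 of the salicylic acid list rose by 1.24 at LD2. SAG101 of that list, AGL24 (flowering time), WRKY53 and SAG29 (leaf senescence), TRY (epidermis and trichome) and PYK10 and EXPA7 (root) were not called in any comparison. The lists of xylem, dividing cell and floral meristem markers had 0 measured genes.

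Arrays of a group also differed among themselves, and the first component of these differences held 31.1% of the variance within groups, the next 17% and 9.7%. Genes with the largest loadings on the first were AT3G13610, AT1G65690, CHI, AT4G16260 and AT4G00700, with standard deviations within groups of 1.18, 1.04, 1.23, 1.12 and 1.01. Loadings were positive for 18 of 18 endoplasmic reticulum folding genes, 9 of 9 ATG8 genes and 17 of 21 immune genes. The scores were 0.42, −0.29 and −0.13 for cat2 hCO2 replicates 3, 2 and 1 and 0.10, −0.35 and 0.25 for Col-0 hCO2 replicates 1, 2 and 3. The next component was led by AT5G16730, NET1D, AT1G65010, NET1B and AT5G40340, with standard deviations of 0.69, 0.66, 0.63, 0.55 and 0.54.

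The 25S ribosomal RNA control averaged 6.72 in Col-0 and 6.64 in cat2 at hCO2, 6.70 and 7.56 at SD2, 6.70 and 7.97 at SD4, 6.67 and 7.27 at LD2, and 6.38 and 7.76 at LD4. The difference between the genotypes was not called in any condition, with adjusted p = 0.984, 0.137, 0.108, 0.578 and 0.0886 (limma with Benjamini-Hochberg over all probe sets). It was positive in each air condition, 0.86, 1.27, 0.61 and 1.38 at SD2, SD4, LD2 and LD4, each with a standard error of 0.38. The lack of a call thus does not show that the control was equal in the genotypes.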
